A study of Sus scrofa with 6 samples.

How the data were processed

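Mononuclear cells were separated on a Ficoll gradient from the blood of untreated, healthy pigs and taken through 10x Chromium library preparation, per the labels' protocols. The series has 6 samples in 3 groups of 2: Duroc RNA-seq, Meishan RNA-seq and Duroc ATAC-seq, all from single cells. Groups and replicate numbers were taken from the sample titles. The 4 RNA-seq samples were not analysed here, so no comparison between breeds was made. For each of the 2 ATAC-seq samples the authors deposited a list of cell barcodes of 16 bases with a suffix and a list of peak positions, and these names and positions are the values used. A matrix of fragments per peak and cell was not used here, so no cells were clustered and no depth could be computed. Barcodes were counted as listed. Doublets were neither called nor removed here, so a barcode can stand for more than 1 cell, and whether they had been removed before is not given in the sources used here.

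The submitters' processing notes name Cell Ranger ATAC 1.2.0, Cell Ranger 3.1.0, Signac 1.1.1, Seurat 4.0.1 and the build Sscrofa11.1. Which tool made the deposited peak lists, and with which threshold, is not given in the sources used here. Each sample has its own peak list, so peaks were used as called per sample. Neighbouring peaks were never closer than 501 bp, the narrowest was 1 bp wide, and all lay on assembled chromosomes. Peak starts were read as counting from 0 and are printed counting from 1. A peak list depends on sequencing depth and on how many cells of each type were captured. A region open in a rare cell type can be missed, and neighbouring peaks can be listed as 1 wide peak in one library and as several in another.

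Gene positions came from an NCBI RefSeq gene table of Sscrofa11.1, which gives a start, an end and a class for each gene but neither strand nor exons. The design fixed before the data were examined asked for promoters and for exon and intron classes. In their place, gene-end windows from 1000 bp outside to 100 bp inside both ends of every gene were used, then gene bodies, then intergenic sequence. A window at a gene's far end, or one that reaches a neighbouring gene's start, counts as well. The length of each chromosome was taken as the last position of any gene or peak on it. Motif enrichment with 25 planned motifs was not run, since it needs a genome sequence, which was not used here.

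Overlap was counted from 1 bp. Each list was placed at random within its chromosomes 100 times with bedtools 2.31.1, and p was the two-sided rank of the observed share, which cannot be below 0.0198. Shared and private peaks were compared by Fisher's exact test. Chance sharing of barcodes was taken from the hypergeometric distribution over the 10x barcode list, whose size is general knowledge and not in the files. Of 338 genes on the 16 lists, 324 matched a protein-coding gene on an assembled chromosome by symbol. ZAP70, TRDC, TRAT1, RHEX, CR2, KLRC1, FPR1, CAMP, PF4, NONO, MB, GRIN1, IL3RA and PLD4 did not. For B2M, TF and GZMA, which have a pair of entries each, the longer was used. Gene-end peaks were tested per list by Fisher's exact test against the other protein-coding genes, with 0.5 added to each cell for the odds ratio only. Locus values were tested against 10000 random lists drawn within 20 bins of locus length, leaving out the list's own genes. The smallest p these can give is 0.000200 before adjustment. Both were adjusted by Benjamini-Hochberg over the 16 lists at a threshold of 0.05. Both treat genes as independent, though neighbouring genes can share peaks. Shares of genes or peaks have 95% Wilson intervals, which cover counting error only.

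The genes named are, for each list, the 3 with the most peaks in the locus among those with a gene-end peak in both replicates, up to 2 without one in either, and those with one in a single replicate. The 10 loci of at least 30 kb with the most peaks per 100 kb and the 5 widest peaks found in both replicates were added by the same fixed rule. Other genes are named as members of a counted list. Some genes that the rule selects, and 1 test on the X chromosome, are not reported here. The alternatives tried were a minimum peak width of 300 bp, merging, another overlap minimum of 50% of both peaks, gene-end windows of 500 and 2000 bp, protein-coding or named genes alone, flanks of 0 and 50 kb, covered bases, matching on gene density, and each replicate alone. A ratio of covered bases between the replicates per list was added after the data were seen, with its own alternatives, and is a description of these 2 libraries.

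The tests were tried on simulated data for the 19550 genes, with 8 changed and 8 unchanged lists of 25 genes. For gene ends, a planted share of 0.98 was called in 8 of 8 lists. For loci, a planted change of 2 times was called in 5 of 8, so a list of that size with a change of 2 times can be missed. For the replicate ratio, a planted change of 1.5 times was called in 8 of 8. None of the unchanged lists was called in any of them. Of 192 further unchanged lists, 6.25%, 1.04% and 4.17% had an unadjusted p under 0.05. Smaller changes, smaller lists and neighbouring genes that differ together were not simulated, so these rates do not cover them. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.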

Results

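The series concerns peripheral blood mononuclear cells (PBMCs), the lymphocytes and monocytes that a density gradient separates from red cells and most granulocytes, taken from Duroc and Meishan pigs. Its title names immune cell heterogeneity and differences between the breeds as its questions. Of 6 samples, 4 are single-cell RNA-seq samples, 2 from each breed, which were not analysed here. The remaining 2 are single-cell ATAC-seq samples of Duroc PBMCs, called replicate 1 and replicate 2 below. ATAC-seq marks open chromatin through the sites that a transposase can reach, and a peak is an interval of the genome where such sites pile up. Nothing in the labels says whether the replicates came from separate pigs, so their spread may be technical. No comparison between breeds was made.

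Replicate 1 listed 9560 cell barcodes and 127556 peaks, and replicate 2 listed 12295 barcodes and 110194 peaks, a mean of 10927.5 ± 1934 barcodes and 118875 ± 12277 peaks (SD, n = 2). The replicate with fewer barcodes thus had more peaks. Peaks covered 154 Mb in replicate 1, 6.34% of the assembled chromosomes, and 126 Mb in replicate 2, 5.17%. Median peak width was 670 bp and 658 bp. A small set of peaks was very wide, with 651 over 10 kb in replicate 1 and 402 in replicate 2. The lists used here carry no fragment counts and no values per cell, so the depth of each library is unknown. The libraries shared 186 barcodes, against 159 expected by chance and a central 95% range of 136 to 184 (two-sided exact hypergeometric test, p = 0.0397).

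The 5 widest peaks found in both replicates, by mean width, lay at ETS1, IKZF1, RASA3, BCL11B and RARA. Neighbouring peaks were never listed closer than 501 bp, and several can be listed as 1. A wide peak therefore need not be open along its whole length. At ETS1, a factor of lymphocyte development (chromosome 9, 55377264 to 55512180, Sscrofa11.1), 1 peak spanned 81.6 kb in replicate 1 and 78.5 kb in replicate 2, running over a gene end and most of the gene body. IKZF1, which encodes the lymphoid regulator Ikaros (chromosome 9, 136372202 to 136464942), held a peak of 48.4 kb and 47.9 kb within the gene. A peak of 42.8 kb and 48.6 kb lay within BCL11B, a factor of T cell commitment (chromosome 7, 120205008 to 120295737). The peak at RARA, a retinoic acid receptor gene on chromosome 12, measured 44.3 kb and 44.1 kb, and the one at RASA3 and the neighbouring LOC106504737 on chromosome 11 measured 64.2 kb and 30.2 kb. At RASA3 the replicates differed by more than 1.5 times, and at the other 4 genes the widths were close.

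**Figure D1:**
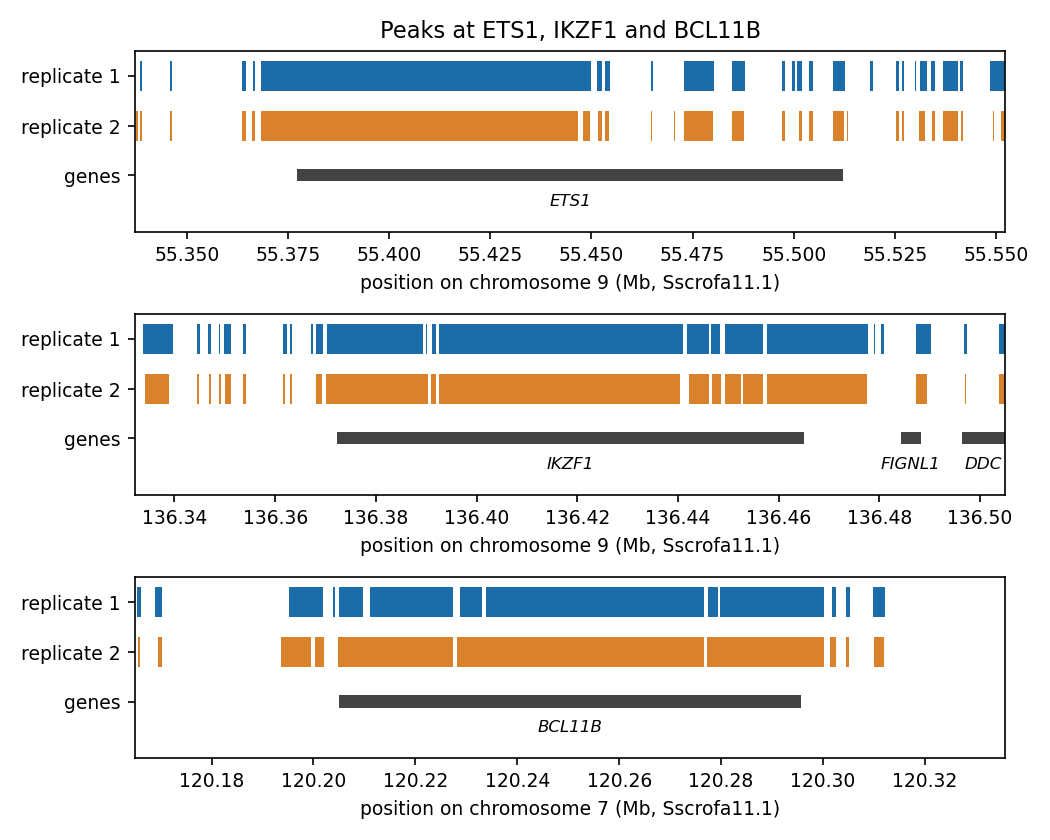
Peaks of replicate 1 (blue) and replicate 2 (orange) over ETS1, IKZF1 and BCL11B with 40 kb on either side; the horizontal axis is the position in Mb, and grey bars are annotated protein-coding genes. The peak at ETS1 spans 81.6 kb in replicate 1 and 78.5 kb in replicate 2, and runs past the left end of the gene in both.

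Most open regions recurred in the other replicate. Of the peaks of replicate 1, 76.6% overlapped a peak of replicate 2 by at least 1 bp, and 93.7% of the peaks of replicate 2 overlapped replicate 1. Wide peaks recurred almost without exception: 99.95% of replicate 1 peaks over 4000 bp were found in replicate 2 (95% Wilson interval 99.9 to 99.98%), whereas 17.6% of those up to 200 bp were (16.8 to 18.3%). In replicate 2 the narrowest class recurred at 70.2% (69.2 to 71.2%). A wide peak has more chance of overlapping the other list by 1 bp, and no random share was computed per width class. Placing each list at random on its own chromosomes 100 times gave a mean overlap of 10.6% for replicate 1 (highest 10.8%) and 12.3% for replicate 2 (highest 12.5%), so the observed shares were 7.22 and 7.59 times the random ones (two-sided permutation p = 0.0198 in each, the smallest that 100 placements can give). When peaks were instead moved by 20 to 500 kb, a check chosen after seeing the data that keeps the broad clustering of peaks, the random overlap rose to 17.6% and 20.7%.

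**Figure D2:**
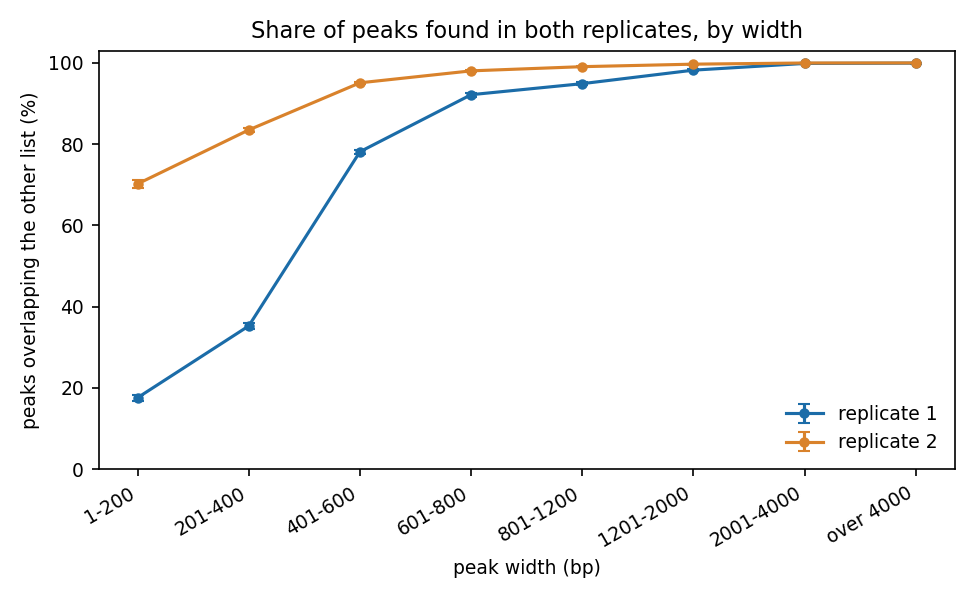
Share of peaks that overlap the other replicate's list (vertical axis, %) by peak width in bp (horizontal axis), for replicate 1 (blue) and replicate 2 (orange), with 95% Wilson intervals as bars. Replicate 1 goes from 17.6% in the narrowest class to 99.95% in the widest, and replicate 2 starts at 70.2%.

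Open regions gathered at the ends of genes. A gene-end window, from 1000 bp outside to 100 bp inside either end of an annotated gene, was touched by 14.1% of replicate 1 peaks and 15.5% of replicate 2 peaks. Random placement gave 5.01% and 4.94%, which makes an excess of 2.82 and 3.13 times (two-sided permutation p = 0.0198 in each, the smallest possible). A further 57.5% and 56.6% of peaks lay elsewhere in a gene body, a small excess over the 54.3% and 54.4% of random placement. The highest placements gave 54.7% and 54.9% (two-sided permutation p = 0.0198 in each). Peaks at gene ends were taken out first, which leaves fewer of the observed peaks for this class than of the placed ones. Intergenic peaks made up 28.3% and 28.0%, against 40.7% in the random placements of each replicate. The gene table used here gives neither strand nor exons, so a gene's start could not be told from its end, nor an exon from an intron.

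Peaks found in both replicates lay at gene ends more often than peaks private to 1 of them. In replicate 1, 17.2% of 97688 shared peaks and 4.08% of 29868 private peaks touched a gene end, an odds ratio of 4.88 (95% interval 4.60 to 5.18). In replicate 2 the shares were 16.2% of 103271 and 4.36% of 6923, an odds ratio of 4.25 (3.78 to 4.77). Private peaks were narrow, with a median of 323 bp against 885 bp for shared peaks in replicate 1 and 298 bp against 699 bp in replicate 2, and they held 6.37% and 1.64% of the covered bases. Fisher's exact test gave p = 1.34e-200 in replicate 2 and a p too small to be represented in replicate 1, though neighbouring peaks are not independent. With 2000 bp windows the odds ratios fell to 2.33 and 2.07, and with an overlap of at least 50% of both peaks to 3.41 and 2.70. A wide peak also has more chance of touching a gene end and the other list.

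Among 19550 protein-coding genes, 13993 (71.6%) had a gene-end peak in both replicates and 4987 (25.5%) in neither. The 16 gene lists fixed before the data were examined cover blood cell types, immune programmes and tissues absent from blood. All 27 measured T cell genes carried a gene-end peak in both replicates, among them CD3D, CD3E and CD3G of the T cell receptor complex and the co-receptors CD4, CD8A and CD8B. All 24 B cell genes did so too, including MS4A1 and PAX5, as did all 23 antigen presentation genes, all 12 plasma cell genes and all 7 gamma-delta T cell genes. The gamma-delta T cell is abundant in pig blood, and its list includes SOX13, BLK and CD163L1. Shares were 25 of 26 for interferon response genes, 25 of 28 for monocyte genes, 24 of 27 for NK and cytotoxic genes and 15 of 18 for dendritic cell genes.

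Each of the 6 lists for granulocytes, erythroid cells, platelets and other tissues had a share below the 71.6% of all protein-coding genes, and 2 of them, liver and skeletal muscle, passed the test as lower. With 2000 bp windows the platelet list turned to an odds ratio above 1, at 1.29 (adjusted exact p = 0.746). Of 25 liver genes, 5 had a gene-end peak in both replicates, namely AMBP, APOA1, F2, HP and TF, and 19 had none in either, among them ALB, the serum albumin gene, and AHSG. Skeletal muscle genes reached 12 of 24, with none at MYF5 or DES, and neuron genes 14 of 24. Erythroid genes reached 7 of 14, with no gene-end peak at HBB, the adult beta-globin gene, GATA1 or ALAS2. Platelet genes reached 7 of 13 and granulocyte genes 9 of 14, the latter including CXCR2, PRTN3 and AZU1, but not ARG1, MMP8 or MPO. Housekeeping genes reached 23 of 24, the exception being LDHA, which had a gene-end peak in replicate 1 alone.

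By Fisher's exact test against all other protein-coding genes (two-sided, Benjamini-Hochberg over 16 lists), 6 lists were higher and 2 lower. The test treats genes as independent, which neighbouring genes need not be. Of the antigen presentation genes, 6 class I genes lie within 825 kb and 8 class II genes within 358 kb of chromosome 7, so its p is too small. By this exact test the T cell list was higher at an odds ratio of 21.9 (adjusted p = 0.00128), antigen presentation at 18.7 (adjusted p = 0.00287) and the B cell list at 19.5 (adjusted p = 0.00233). Interferon response (adjusted p = 0.0114), housekeeping (adjusted p = 0.0147) and plasma cell genes (adjusted p = 0.0494) were also higher, by exact test. Where every gene of a list has a peak, the odds ratio is set by list size, background share and the 0.5 added to each cell. The odds ratios of the T cell, B cell, antigen presentation, plasma cell and gamma-delta T cell lists are therefore not measures of strength. The liver list was lower at an odds ratio of 0.106 (adjusted exact p = 2.04e-06), and skeletal muscle at 0.397 (adjusted p = 0.0494). By exact test the skeletal muscle call was lost with 2000 bp windows (odds ratio 0.456, adjusted p = 0.118) and with peaks of at least 300 bp (0.412, adjusted p = 0.0712), as was the plasma cell call (odds ratio 7.005, adjusted p = 0.118, and 10.3, adjusted p = 0.0543). The monocyte (odds ratio 2.90, adjusted p = 0.0648), NK and cytotoxic (2.78, adjusted p = 0.0851), gamma-delta T cell (5.96, adjusted p = 0.245), dendritic cell (1.76, adjusted p = 0.461), erythroid (0.397, adjusted p = 0.119), platelet (0.458, adjusted p = 0.245), neuron (0.548, adjusted p = 0.232) and granulocyte (0.686, adjusted p = 0.558) lists did not pass the exact test. The exact test called the monocyte list with replicate 1 alone (odds ratio 6.54, adjusted p = 0.00928) and the NK and cytotoxic list with 2000 bp windows (4.95, adjusted p = 0.0417). The odds ratios of interferon response and housekeeping genes, 6.76 and 6.23, rose to 14.9 and 13.7 with these windows and to 18.9 and 17.5 with replicate 1 alone. In replicate 1 all 26 and all 24 of these genes had a peak, so the added 0.5 sets the value. The B cell list, also of 24 genes, gave the same 13.7 and 17.5 as the housekeeping list. The odds ratio of erythroid genes moved to 0.653 with the 2000 bp windows. Against genes with a symbol other than an automatic locus name, the T cell odds ratio fell to 14.4, the B cell one to 12.8 and that of antigen presentation to 12.3, the exact test no longer called interferon response (adjusted p = 0.0579), housekeeping (adjusted p = 0.0699) and plasma cell (adjusted p = 0.209) genes, and it called erythroid (adjusted p = 0.0371) and neuron (adjusted p = 0.0449) genes lower. Windows of the same size 20 kb outside the genes held a peak for 39.9% of genes in replicate 1 and 35.4% in replicate 2. Gene-end windows did for 73.7% and 72.3% of the protein-coding genes in these replicates. The outside windows can fall on neighbouring genes and their ends, so their share is not a level for chromatin away from genes.

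**Figure D3:**
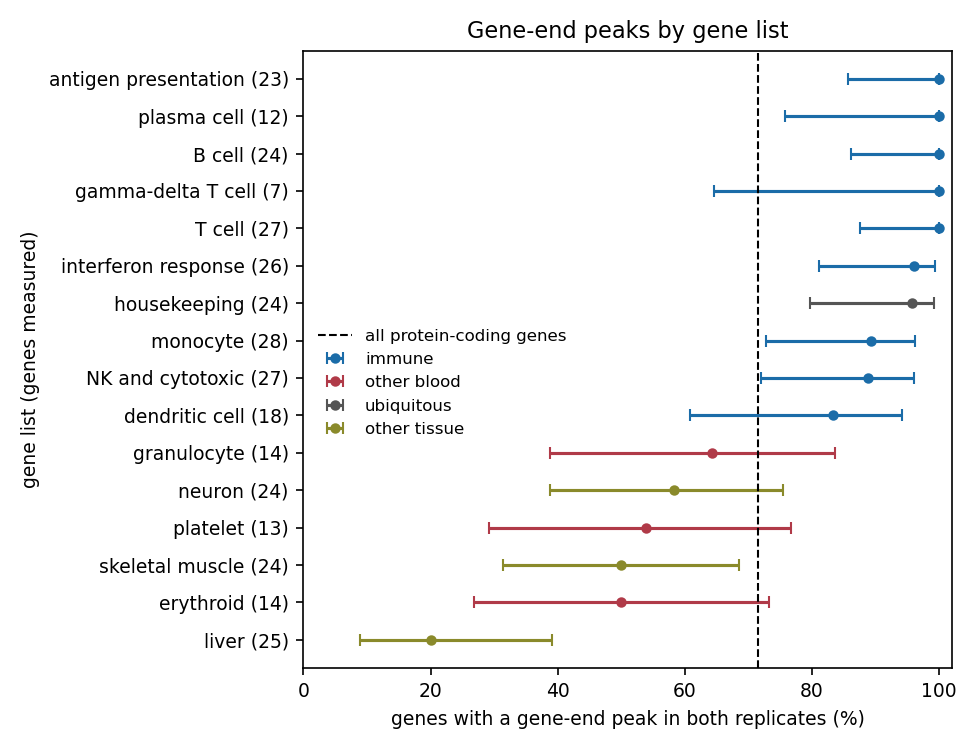
Share of the genes of each list with a gene-end peak in both replicates (horizontal axis, %), with 95% Wilson intervals as bars and the number of genes measured in brackets; colours give the kind of list and the dashed line marks all 19550 protein-coding genes at 71.6%. The T cell, B cell, plasma cell, antigen presentation and gamma-delta T cell lists stand at 100% and the liver list at 5 of 25 genes.

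Around the genes of the T cell, B cell and dendritic cell lists, open regions were also more numerous over the whole locus, taken as the gene body and 10 kb on either side. The median T cell gene held 8.5 peaks (replicate mean; 8 in each replicate taken alone), against a mean of 4.85 for random gene lists matched on locus length. B cell genes held 7.5 against 4.51, and dendritic cell genes 7.75 against 4.89 (9.5 in replicate 1 and 8 in replicate 2). LEF1, a partner of beta-catenin in T cells, had 33 peaks in replicate 1 and 35 in replicate 2, the adaptor gene SKAP1 32 in each, and THEMIS, needed for thymic selection, 26 and 23. Of the B cell genes, EBF1, which sets B cell identity, held 37 and 30, the signalling scaffold gene BANK1 28 and 21, and CIITA, the master regulator of MHC class II genes, 17 and 23. RUNX2 held 39 and 40, TCF4, the factor of plasmacytoid dendritic cells, 46 and 27, and the chemokine receptor gene XCR1 23 and 22.

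The genes named for each list are those with the most peaks, so their counts are high by choice and were not tested one by one. Outside the immune lists the same choice gave 24 and 21 peaks at the muscle gene RYR1 and 25 and 23 at the housekeeping gene RAB7A. For gamma-delta T cells BLK, a Src family kinase gene, held 18 and 7 peaks, IL7R 11 and 13, and CD163L1, a scavenger receptor gene of the WC1 family, 7 and 10. Among cytotoxic genes CD244 held 15 and 16, IL2RB 13 and 15, and the granzyme gene GZMA 8 in each. GZMA has a second entry in the gene table, so its values are uncertain. The monocyte integrin gene ITGAM held 18 and 17, TREM1 11 and 13, and TGFBI 9 and 10, while VCAN held 16 and 10 with no gene-end peak. In the plasma cell list CD38 held 9 and 18, PRDM1, the plasma cell master regulator, 11 and 14, and IRF4 7 and 8. NLRC5, the activator of MHC class I genes, held 19 and 29, and SLA-1, a class I gene of the swine leukocyte antigen (SLA) complex, 20 and 21. Of the interferon response genes, the RNA sensor gene DDX58 held 13 and 10, and GBP1 12 and 6. A count need not follow the bases covered. BLK had 48.8 kb covered in replicate 1 and 63.9 kb in replicate 2, the reverse of its counts. So did NLRC5 with 86.6 and 65.2 kb, CD38 with 41.5 and 36.8 kb and CIITA with 56.1 and 38.4 kb. At DDX58 (8.93 and 7.14 kb) and GBP1 (20.7 and 10.7 kb) counts and bases went the same way.

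Against 10000 random lists, the T cell list at 1.75 times the random mean (adjusted p = 0.00320), the B cell list at 1.66 (adjusted p = 0.00320) and the dendritic cell list at 1.59 (adjusted p = 0.0427) were higher by a two-sided permutation test with Benjamini-Hochberg adjustment over 16 lists. No list was lower after adjustment, and 1, the liver list at 0.602 times, was at an unadjusted p under 0.05 (adjusted permutation p = 0.0809). Monocyte (1.40 times, adjusted p = 0.0742), antigen presentation (1.42, adjusted p = 0.0742), NK and cytotoxic (1.42, adjusted p = 0.0809), gamma-delta T cell (1.69, adjusted p = 0.133), granulocyte (1.33, adjusted p = 0.278), interferon response (1.24, adjusted p = 0.291), plasma cell (1.28, adjusted p = 0.429), platelet (1.28, adjusted p = 0.431), skeletal muscle (0.779, adjusted p = 0.431), erythroid (0.991, adjusted p = 1), neuron (0.940, adjusted p = 1) and housekeeping (0.962, adjusted p = 1) lists did not pass the permutation test. Measured in bases covered instead of peaks, the gamma-delta T cell list at 3.80 times (adjusted p = 0.000800), antigen presentation at 2.68 (adjusted p = 0.000800) and interferon response at 1.87 (adjusted p = 0.00366) passed as higher and the liver list at 0.306 (adjusted p = 0.00256) as lower, by the same permutation test, and the T cell list stood at 3.67 times and the B cell list at 2.67. The gamma-delta T cell median, over 7 genes, was the 23.3 kb of IL7R, which is also on the T cell list and equals that list's median. This pass therefore does not set gamma-delta T cell genes apart from T cell genes. Without flanks the granulocyte list turned to 0.766 times (adjusted permutation p = 1), the platelet list to 0.989 and the erythroid list moved to 0.642 (adjusted permutation p = 0.982), and in covered bases granulocyte genes stood at 0.931 (adjusted permutation p = 0.882) and housekeeping genes at 1.44 (adjusted permutation p = 0.123). With 50 kb flanks the NK and cytotoxic (1.53 times, adjusted p = 0.000800), antigen presentation (1.77, adjusted p = 0.000800), monocyte (1.40, adjusted p = 0.0299) and interferon response (1.34, adjusted p = 0.0375) lists passed the permutation test as higher. With replicate 1 alone the monocyte list passed the permutation test (1.55 times, adjusted p = 0.0304), and with replicate 2 alone antigen presentation did (1.65, adjusted p = 0.0152). The dendritic cell call was lost when lists were also matched on gene density, at 1.52 times in place of 1.59 (adjusted permutation p = 0.0648), and without flanks the list stood at 2.44 times (adjusted p = 0.00320).

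**Figure D4:**
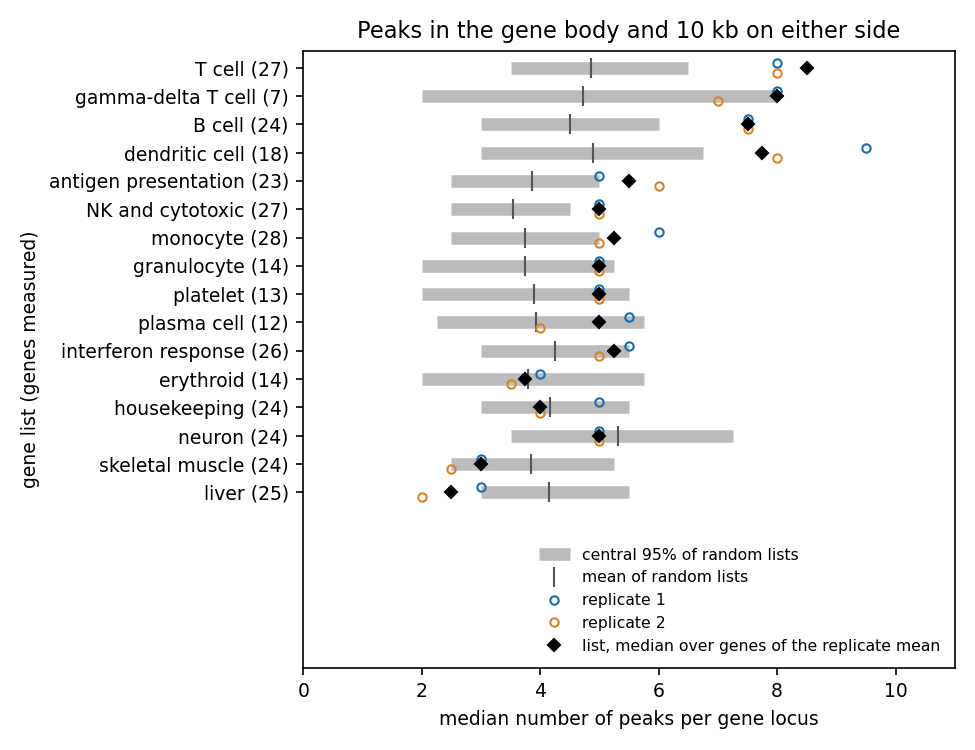
Median number of peaks per gene locus (horizontal axis) for each gene list, with the number of genes in brackets. Diamonds give the median over genes of the replicate mean, open circles each replicate, grey bars the central 95% of 10000 random lists of matched locus length and ticks their mean; T cell genes stand at 8.5 against 4.85.

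Genome-wide, the gene loci of at least 30 kb with the most peaks for their length held 32.6 to 35.9 peaks per 100 kb. They were SCN2B on chromosome 9 at 35.9, RPP14 with the overlapping LOC100515579 on chromosome 13 at 34.7, CARD19 on chromosome 3 at 34.1, KIAA0040 on chromosome 9 at 33.9, the GTPase gene CDC42 on chromosome 6 at 33.7, GGA3 on chromosome 12 at 33.3, LOC110259698 on chromosome 2 at 33.0, NFKB1, a subunit gene of the NF-kappa-B factor, on chromosome 8 at 32.9, and PLVAP on chromosome 2 at 32.6.

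The SLA complex, whose class I and class II genes are also on the antigen presentation list, was densely open. The 825 kb span of the 6 class I genes on chromosome 7 (22824137 to 23649342) held 130 peaks in replicate 1 and 120 in replicate 2, or 15.8 and 14.5 per 100 kb, above 98.3% and 98.4% of windows of that length. The 358 kb span of the 8 class II genes (24825037 to 25182665) held 67 and 71 peaks, above 98.8% and 99.7% of windows, and peaks covered 49.7% and 39.3% of it. Segments annotated as V segments or C regions, the building blocks of T cell receptors and immunoglobulins, formed 5 clusters. The cluster on chromosome 9 (108678512 to 108784323) was the most open, with 26 and 27 peaks in 106 kb, above 99.3% and 99.7% of windows. Those on chromosomes 14, 18 and 7 lay above 91.1%, 88.9% and 81.9% of windows in replicate 1 and 88.0%, 91.2% and 91.1% in replicate 2, and the cluster on chromosome 3 above 68.5% and 73.3%. The clusters are named here by position, since the annotation does not say which receptor each belongs to. All these spans were ranked among every window of their length on the assembled chromosomes, without matching on gene number. Peaks gather at gene ends, so the ranks do not tell dense peaks from dense genes.

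On the X chromosome open regions were sparse. X held 28.6 peaks per Mb in replicate 1 and 24.3 in replicate 2, below every autosome, whose values ran from 39.0 to 91.1 and from 33.5 to 82.2. X was 0.523 and 0.513 times the autosomal mean of 54.7 and 47.3 peaks per Mb. X also has fewer protein-coding genes, 6.05 per Mb against 8.26 on the autosomes. Per protein-coding gene X held 4.73 and 4.01 peaks, with the lowest autosome at 4.56 and 4.04. The autosomes together held 6.62 and 5.72 per gene. The Y chromosome held 60 peaks in replicate 1 and 45 in replicate 2. With 1 value per replicate, these values were not tested.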

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

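The replicate ratio, its alternatives and the moved-peak check were chosen after the data were seen. Of 325 recomputed values, 275 kept their side of the threshold or moved little, among them 19 list values called in neither setting that changed direction, 19 lost a call, 15 gained one, 13 counts or values moved and 3, called in either setting, reversed. The 275 include alternatives that could not change a value, such as merging close peaks. They also include the moved-peak check, which repeats the observed share and changes only the random one. Overlap, location and shared against private peaks kept their direction and call under all alternatives run that could change them. With peaks of at least 300 bp, 110895 and 96810 peaks were left, Y held 50 and 39, and X held 25.1 per Mb in replicate 1. For gene-end peaks, lists lower went from 2 to 1 with 2000 bp windows and to 1 with peaks of at least 300 bp, skeletal muscle being lost in both. Against named genes alone 3 lists were higher and 4 lower, a smaller background with fewer unnamed loci. Leaving out a replicate gave 5 to 6 lists higher and 2 lower. By exact test, the plasma cell call (adjusted p = 0.0494) was lost in each of these alternatives, at adjusted p from 0.0543 to 0.209. For locus peaks, lists higher went from 3 to 7 with 50 kb flanks and to 6 with covered bases, where 1 was lower; leaving out a replicate gave 4 higher and 0 lower.

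For the replicate ratio, 3 lists were higher and 2 lower in covered bases. By number of peaks 0 were higher and 1 lower (2 and 2 at an unadjusted permutation p under 0.05), matched on covered bases 1 was higher, and without flanks 1 was higher and 1 lower. By number of peaks the log2 ratio relative to random lists reversed to 0.46 for gamma-delta T cell, -0.044 for NK and cytotoxic and -0.33 for antigen presentation genes. The cause was not tested for the moved and reversed values, though 1 wide peak counts as fewer peaks than several narrow ones. Motif enrichment and its 5 alternatives were not run. Merging peaks closer than 500 bp, keeping assembled chromosomes or unique barcodes, and dropping barcode suffixes changed nothing, so they test nothing. Depth is unknown for both libraries and limits which narrow peaks can be called. No paired analysis was possible because 1 group was analysed, and no other group with the same replicate numbers.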

Other observations

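The gene families, the comparison of replicates by locus, the Y segment and the test of its recurrence were chosen after the data were seen. Families were set by symbol alone, so a family can hold other genes, as IRF2BP1, IRF2BP2 and IRF2BPL in that of the interferon regulatory factors. The exact test used for families treats genes as independent, which neighbouring genes of a family need not be. Of 13 gene families, 3 differed from the other genes in gene-end peaks. Of 35 keratin genes, which build epithelial filaments, 4 had a gene-end peak in both replicates (KRT10, KRT18, KRT25 and KRT28) and 31 had none (Fisher's exact test, adjusted p = 2.06e-12). Genes grouped as ribosomal protein genes by symbol had one in 88 of 91 (adjusted p = 4.25e-09) and zinc finger genes named ZNF in 220 of 254 (adjusted p = 6.29e-08), both by exact test. The other 10 families did not pass the exact test (adjusted p from 0.0802 to 0.607). Among these, chemokine receptor genes had one in 15 of 16 (adjusted exact p = 0.119), Toll-like receptor genes in 9 of 10 (adjusted exact p = 0.390), chemokine genes in 19 of 29 and interleukin genes in 28 of 41. Among other gene classes, 40.1% of 5425 lncRNA genes and 13.05% of 2307 pseudogenes had a gene-end peak in both replicates.

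Covered bases at blood cell genes did not differ between the replicates in 1 common ratio. Replicate 1 covered more bases at most loci: of 7263 protein-coding gene loci with a mean of at least 8 kb covered, 580 (7.99%) had more in replicate 2. Gamma-delta T cell genes went the other way, with 188 kb in replicate 1 and 228 kb in replicate 2 over 7 loci, 5 of them higher in replicate 2. SOX13, a factor of that lineage, lay wholly inside 1 peak of 63.6 kb in replicate 2 and held 15 peaks covering 40.7 kb in replicate 1. BLK had 63.9 kb in replicate 2 and 48.8 kb in replicate 1, GATA3 43.9 kb and 34.6 kb, and CD163L1 8383 bp and 3677 bp. GATA3 and IL7R stand on the T cell list too, and BLK on the B cell list. Monocyte genes had more bases in replicate 1 at all 28 loci, 317 kb against 228 kb, as at ITGAM with 25.4 kb and 12.4 kb and SIRPA with 14.5 kb and 6118 bp, and NK and cytotoxic genes at 26 of 27, 335 kb against 253 kb. These tallies do not set them apart, since housekeeping genes had more in replicate 1 at 24 of 24 loci, interferon response genes at 26 of 26, platelet genes at 13 of 13 and B cell genes at 23 of 24. The log2 ratio of replicate 1 to replicate 2 was -0.28 for gamma-delta T cell, 0.06 for T cell, 0.48 for monocyte, 0.40 for NK and cytotoxic and 0.43 for granulocyte genes. These lay at percentiles 0.030, 0.23, 99.97, 99.98 and 99.71 of 10000 random lists of matched length. The B cell (0.29), dendritic cell (0.39), plasma cell (0.28), antigen presentation (0.27), interferon response (0.34), erythroid (0.21), platelet (0.36), housekeeping (0.27), liver (0.38), neuron (0.22) and skeletal muscle (0.24) lists were not called after adjustment, though with 50 kb flanks liver genes, of a tissue absent from blood, were (0.14 relative to random lists, adjusted permutation p = 0.00800). Relative to random lists, the T cell ratio of -0.21 and the monocyte ratio of 0.24 were no longer called without flanks, where they stood about as large at -0.23 and 0.22 (adjusted permutation p = 0.0808 in each), or by number of peaks, at -0.13 and 0.17. The NK and cytotoxic ratio of 0.20 was no longer called when matched on covered bases, at 0.14, and reversed by number of peaks. The granulocyte ratio of 0.21 was not called in 4 of 5 alternatives, at 0.045 to 0.18. The gamma-delta T cell ratio of -0.53 reversed by number of peaks, to 0.46.

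Replicate 1 listed more private peaks, 29868 against 6923. A deeper library or a looser threshold predicts narrow private peaks spread over the genome, and private peaks of replicate 1 had 0.365 times the median width of shared ones, at 0.888 to 1.10 times the genome-wide share on each of the 18 autosomes. Private peaks of replicate 2 were narrow as well, at 0.426 times, and a wide peak has more chance of meeting the other list, so the widths do not decide on depth or threshold, which stay open. A different mix of blood cells stays open too: by number of peaks, 3 of 10 cell type lists lay outside the central 95% of random lists, none after adjustment, and by covered bases 5 did. The monocyte list alone lay outside on the same side by both measures, and the gamma-delta T cell list lay outside on opposite sides. The number of peaks falls where regions join, so the cell mix cannot be told apart from depth or threshold here.

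On the Y chromosome, a segment from 8937949 to 10165732 with 16 annotated genes, chosen after its values were seen, held 6 peaks in replicate 1, at or within 1 kb of EIF1AY and 5 genes with automatic locus names, and 0 in replicate 2. Elsewhere on Y, 40 of 54 replicate 1 peaks recurred. From autosomal peaks of like width, the probability that none of the 6 recurs is 5.74e-05, and of 123805 runs of 6 neighbouring autosomal peaks, 126 (0.102%) had none recurring, 3 of them at widths that made this as improbable. The segment was picked because replicate 2 had no peak there, and Y, unlike an autosome, is single copy, so these values do not decide on lower depth of replicate 2. Depth stays open, as does a difference in sex between the replicates, a candidate explanation that the labels do not address and of which no test is reported here.

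X held about as few peaks relative to autosomes in each replicate, 0.523 and 0.513 times. Fewer genes on X predict that X lies within the autosomal range per gene in both replicates. Its 4.73 peaks per gene in replicate 1 did, above chromosome 2 alone at 4.56, while its 4.01 in replicate 2 fell just below the lowest autosome at 4.04. The autosomes together held 6.62 and 5.72 per gene, so X was below that mean in both replicates. A place within the range does not show that gene number accounts for the difference, because 1 chromosome sets its low end. A single X in males predicts peaks at Y-linked genes outside the part shared with X, and fewer peaks per gene on X than on every autosome, both in each replicate. Fewer peaks per gene than on every autosome held in replicate 2 alone, by the narrow margin of 4.01 against 4.04. That replicate had 0 peaks in the Y segment from 8937949 to 10165732, where replicate 1 had 6. Y held 60 and 45 peaks, and 40 of the 54 outside the segment from 8937949 to 10165732 recurred, but the gene table does not mark the part of Y shared with X. Neither explanation is decided by these values.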
